A study of Dunaliella tertiolecta UTEX 'LB 999' with 2 samples.

How the data were processed

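RNA from 2 culture samples, taken 4 h and 8 h after the light shift, was made into stranded mRNA libraries with a TruSeq kit, per the labels' protocols. The submitters' processing notes name Partek, with no version. The aligner, the assembler and the reference are not given in the sources used here. The files are 2 lists of contigs, one of contigs higher and one of contigs lower at 8 h, and contigs outside the lists were not analysed here. Contigs carry the symbol, description and identifier of a Chlamydomonas reinhardtii protein, per the file headers, so a gene name here is that of the best hit in another alga. For 25 contigs the E value of that hit was over 1e-20, and for 1 none was given. Positions are those within a contig, with no place in a genome, and 3 proteins were the best hit of 2 contigs.

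The authors' deposited means are RPKM, reads per kilobase of contig scaled to the library's reads. The columns of means are headed annotation and Bacillus_subtilis, which name neither sample, and nothing in the labels explains these headings. The first was taken as 8 h and the second as 4 h, as numerator and denominator of the ratio whose contrast cell reads 8 vs 4. That assignment rests on the contrast and the ratio alone. The authors' deposited table gives that ratio, its natural log, a p-value and a step-up FDR. It writes the fold change in the lower list as a signed score, per the file headers. The authors' deposited table also holds a raw total, an estimated count that is not always whole and covers all libraries in their model. Every fold in the authors' deposited table was at least 2 and every p under 0.05, while the FDR there reached 0.246. In 228 of 234 rows, the p in the authors' deposited table was matched within 1% by a Wald test that takes RPKM values as Poisson counts, and the largest difference was 6.41%. That test does not use the number of reads, so a short contig passes it on fewer reads. Of 97 contigs under 1000 bases 37 had an exact p under 0.05 on their reads (38.1%), and of 137 longer ones 105 (76.6%).

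Reads were recovered from RPKM, contig length and the raw maximum per library. RPKM times length over reads was the same, within 0.01%, in all 134 rows of the higher list and in 97 of the lower list. In the other 3 rows the maximum lay in another library. Of 161 contigs with whole raw totals, all 161 gave whole reads in both libraries, within 0.001 reads. The other 73 had fractional totals, and their reads were rounded for tests and intervals. Folds were the ratios of the authors' RPKM means. Their 95% intervals came from Clopper-Pearson intervals of the 8 h share of reads. The design set beforehand held no test. The two-sided exact binomial test on reads was added after the values were seen, is not adjusted, and runs on contigs the authors had already chosen for a large difference. Its p and the interval are built differently, so a p under 0.05 can stand beside an interval that reaches 1. In simulations of the 234 contigs with known folds, the intervals held the true ratio in 96.8% to 97.3% of draws. The test called 3.53% of unchanged contigs, 41.2% at a true fold of 2, 72.2% at 3 and 91.1% at 5. The simulated draws were not selected for a large difference, as the listed contigs were. These rates therefore need not hold for the listed contigs, whose folds may be inflated by that selection.

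Functional groups were 34 keyword lists fixed before the data were examined and matched to names and descriptions. A contig can be in several. The result of 1 list is not reported here. The share of higher contigs was given an exact binomial interval and, for the 10 lists of at least 5 contigs, a percentile among 10000 random lists of the same size, drawn from the listed contigs and matched on 5 bins of mean RPKM. Percentiles describe these libraries and were not adjusted for the number of lists. Some matches were wrong by wording. They were kept as fixed, and an alternative with 11 removals and 19 additions by hand was chosen after the data were seen. The rule for named genes took the 10 largest folds per direction with an annotated function, and the largest fold in the majority direction of each list of at least 3 contigs, which gave 19 higher and 12 lower contigs. They needed 10 reads or a level of 1 RPKM in the higher library, which every contig met by its level. Other contigs were named as examples after their values were seen. Alternatives were a 4-fold limit, an FDR under 0.001, repeated names collapsed, annotated contigs only, at least 10 reads, an annotated background and pseudocounts of 1 and 0.1 RPKM. Added after the data were seen were the exact test, an FDR under 0.05, an E value under 1e-20 and the hand-read lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.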

Results

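Messenger RNA was sequenced from the unicellular green alga Dunaliella tertiolecta, a wall-less flagellate that lives in salt water. Strain UTEX LB-999 was kept in a chemostat, a culture held at steady state by constant inflow, at 25 °C in medium with 0.5 M NaCl under a photon flux of 40 µmol m-2 s-1. The flux was then set to 400 µmol m-2 s-1, and RNA was taken after 4 h and after 8 h, with 1 library per time point. The data used here are lists of 234 transcript contigs that the authors reported as different between these 2 libraries, 134 of them higher and 100 lower at 8 h. The RPKM values correspond to 674129 reads for the 8 h library and 556037 for the 4 h library. The listed contigs held 4930 and 3930 of these reads, or 0.731% and 0.707%. With 1 library per time point there was no replicate spread, so every difference below is between these 2 libraries and has no replicate check. Intervals of folds are 95% exact intervals on the recovered reads and cover counting error only. Intervals of the share higher in a list are 95% exact binomial intervals on numbers of contigs. They treat contigs as independent and do not cover error in the reads.

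The comparison asked which transcripts were at other levels at 8 h than at 4 h after the light shift. In the 8 h library, transcripts for flagella, mitochondrial respiration, glycolysis and ribosomal proteins were among those listed as higher. Transcripts for histones, DNA replication, cell division and the light-harvesting antenna were among those listed as lower. Apart from flagella and histones, these lists held 2 to 6 contigs each, and their intervals included the share of all listed contigs that were higher. The median log2 ratio was 1.46 among the higher contigs (quartiles 1.25 and 1.79) and -1.42 among the lower ones (quartiles -1.67 and -1.22). Most rested on few reads, with a median of 16 reads at 8 h against 5 at 4 h in the higher list, and 6.11 against 15 in the lower list. In an exact binomial test on these reads, which compares the libraries and not the conditions, 78 of the 134 higher and 64 of the 100 lower contigs had an unadjusted p under 0.05.

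**Figure D1:**
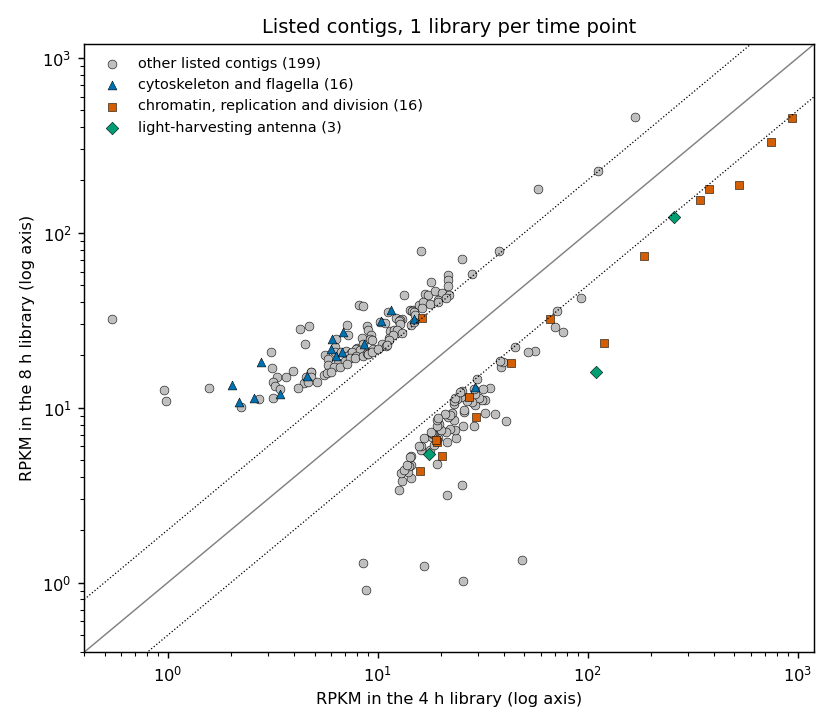
Authors' mean RPKM of each of the 234 listed contigs in the 4 h library (x, log axis) and the 8 h library (y, log axis), with the line of equal levels and dotted lines at 2-fold. Contigs of the cytoskeleton and flagella list (16) lie above the line but for 1, and those for chromatin, replication and division (16) below it but for 1. The latter set joins the lists for histones and chromatin, DNA replication, and cell cycle and division. This union was not in the design set beforehand.

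Flagellar genes gave more higher contigs than any other annotated list. Of 16 listed contigs of the cytoskeleton and flagella, 15 were higher at 8 h (93.8%, exact binomial interval 69.8% to 99.8%), against 57.3% of all listed contigs. That share lay at percentile 99.9 of 10000 random lists matched on expression. FAP115 and FAP81, flagellar associated proteins, were each 6.60-fold higher (interval 1.55 to 59.2) on 16 reads against 2. FAP189 was 4.07-fold higher (2.02 to 8.95), RIB72, a protein of the microtubule ribbon in the flagellar axoneme, 3.61-fold (1.64 to 9.005), and ODA6, an intermediate chain of the outer dynein arm that drives flagellar beating, 3.15-fold (1.59 to 6.78). IFT80, a subunit of the intraflagellar transport machinery that lay outside the list's wording, was 4.40-fold higher (1.26 to 23.6). Of the 15 higher contigs in the list, 11 had an exact p under 0.05, and the folds of the 15 ran from 2.14 to 6.60. The exception was a kinesin 5 contig, whose relatives act in the mitotic spindle, at 2.24-fold lower (1.36 to 3.76).

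Chromatin genes went the other way. Of 12 listed contigs for histones and chromatin, 11 were lower at 8 h, so that 8.33% were higher (interval 0.211% to 38.5%), at percentile 0.02 of the matched random lists. HTA4, a histone H2A, was 5.14-fold lower (2.49 to 13.6), at an authors' mean of 23.4 RPKM at 8 h and 120.2 at 4 h. HTB2, from the histone H2B family, was 2.79-fold lower (2.01 to 3.93). HFO26, a histone that stood at 936 RPKM at 4 h and 455 at 8 h, was 2.06-fold lower (1.65 to 2.58). Across the 8 core histone contigs the summed mean was 3296 RPKM at 4 h and 1434 at 8 h. The raw totals of all 8 were fractional, so their reads were shared with other contigs and the split among copies is uncertain. The histone contigs are thus not independent, as the interval of the share and the percentile take them to be. HTB2 and HTB26 also had the same best hit, as did HFO26 and another histone contig. The contig listed as higher was a histone deacetylase, at 2.00-fold (0.948 to 4.16).

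Genes of DNA synthesis and division were listed as lower without exception in the lists fixed beforehand. RPA70B, a subunit of the protein that binds single-stranded DNA, was 2.38-fold lower (1.52 to 3.80), and MCM5, part of the replicative helicase, 2.34-fold lower (1.35 to 4.28). They were the 2 listed contigs for DNA replication. The cell cycle and division list also held 2 contigs, both lower. With 2 contigs, the interval of the share higher in each list was 0% to 84.2%, which includes the share of all listed contigs. SMC4, a condensin subunit, was 3.84-fold lower (1.96 to 8.07), and CDKA1, the cyclin-dependent kinase of the cell cycle, 3.64-fold lower (1.26 to 12.8). Outside these 2 lists, MIND1, which places the division site of chloroplasts, was 3.94-fold lower (1.73 to 10.1). CDD1, a cytidine deaminase that also lay outside them, was 13.3-fold lower (1.94 to 574) on 1 read against 11. In the other direction, a microtubule-associated protein 65-8 contig outside these 2 lists, of a family that acts in cytokinesis, was 3.15-fold higher.

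Contigs for photosynthesis were listed in both directions. All 3 contigs matched to the light-harvesting antenna list were lower at 8 h. The interval of the share higher, 0% to 70.8%, included the share of all listed contigs. LHCBM3, a chlorophyll-binding protein of the photosystem II antenna, was 6.83-fold lower (3.69 to 13.2), with an authors' mean of 16.04 RPKM at 8 h and 109.6 at 4 h. LHCBM4 was 2.08-fold lower (1.59 to 2.72), at 123.5 against 256.8 RPKM. ELI3, by its symbol an early light-inducible protein and not an antenna subunit, was 3.23-fold lower on 3 reads against 8 (0.776 to 18.9). The raw totals of LHCBM3 and LHCBM4 were fractional too, so that reads shared between antenna genes leave their single values uncertain. Of 4 contigs matched as photosystem core subunits 1 was higher, but LHCBM3 and LHCBM4 are antenna proteins matched by wording. The PsbP-family contigs that were left, CGLD14 and PSBP9, went opposite ways on at most 10 reads. GUN4, which binds chlorophyll precursors, was the 1 contig matched to chlorophyll and haem synthesis and 5.10-fold higher (1.10 to 45.5). A contig similar to Crd1, a cyclase of chlorophyll synthesis that the wording missed, was 2.21-fold lower (1.55 to 3.18) on 50 reads against 91. No listed contig matched the keywords for photoprotection, photosynthetic electron transport and ATP synthase, carotenoid and isoprenoid synthesis, or photoreceptors and clock. That holds for the wording only, since chloroplast contigs outside these keywords were listed in both directions. Besides ELI3, a gamma-tocopherol methyltransferase was 3.03-fold lower. PTOX2, of the alternative oxidase family, was 2.42-fold higher, and CCB3, for cofactor assembly of the b6f complex, 2.06-fold higher. A pseudo-response regulator 3 contig, of a family with members in plant clocks, was missed by the wording and was 2.30-fold higher (1.34 to 4.12). A response regulator with a CCT motif was 2.75-fold higher (0.708 to 15.5).

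The lists for carbon metabolism were small. All 6 contigs matched to glycolysis and the TCA cycle were higher (interval 54.1% to 100%), at percentile 98.0 of the matched random lists. The interval included the 57.3% of all listed contigs, and 95% of the random lists lay between 16.7% and 100%. Of the 6, 5 had an exact p under 0.05. They included a pyruvate kinase at 2.72-fold (1.53 to 5.55) and PEPC1, a phosphoenolpyruvate carboxylase, at 2.38-fold (1.42 to 4.20). The member with the largest fold, at 5.36 (1.21 to 48.9), was a 2-oxoglutarate dependent oxygenase, which is not a TCA cycle enzyme. In the Calvin cycle list both contigs were higher. GAP1a, the plastid glyceraldehyde-3-phosphate dehydrogenase, stood at 459 RPKM at 8 h and 169 at 4 h, 2.72-fold higher (2.26 to 3.28). The other, an ARF-GAP domain protein, was matched by its letters alone. CAH1, an alpha carbonic anhydrase and the 1 listed contig for inorganic carbon uptake, was 2.05-fold higher (0.921 to 5.65).

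Of the 3 contigs matched to the starch metabolism list 1 was higher and 2 were lower. SBE2, a starch branching enzyme, had 24.7 reads at 8 h and 0.344 at 4 h. Its 4 h reads round to 0, so the counting interval of its fold began at 5.19 and had no upper end. Its raw total was fractional, so reads shared with other transcripts leave this value uncertain. Starch synthase 3 was 2.06-fold lower (1.32 to 3.20), and a phosphoglucan, water dikinase contig, from starch breakdown, 2.67-fold lower (0.854 to 9.79). Outside the list's wording, the large subunit of ADP-glucose pyrophosphorylase, the enzyme that commits carbon to starch, was 9.70-fold lower (1.30 to 430) on 1 read against 8. Of 5 contigs for fatty acid and lipid synthesis 4 were higher (interval 28.4% to 99.5%), at percentile 80.8. The largest was a GDSL-like lipase at 3.76-fold (0.890 to 18.2), and the lower one was SQD2, which makes sulfolipid, at 2.27-fold (1.20 to 4.47).

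The lists for respiration and protein synthesis held higher contigs only. All 6 contigs of the mitochondrial respiration list were higher (interval 54.1% to 100%), at percentile 98.5, and 3 had an exact p under 0.05. This interval included the share of all listed contigs too, and the random lists ran over the same range. NUOA1, a small subunit of complex I, was 4.95-fold higher (1.10 to 45.5), and NUOB12, another, 2.47-fold (1.08 to 6.37). PTOX2, at 2.42-fold (1.35 to 4.58), is a plastid oxidase. All 4 contigs matched as ribosomal proteins were higher (interval 39.8% to 100%, which includes the share of all listed contigs). Among them were an L24e family protein at 2.91-fold (1.62 to 5.57) and the mitochondrial MRPS19 at 3.30-fold (0.890 to 18.2). The description of another, CLPT1, also names a Clp protease adaptor, and 3 contigs were left when the list was read by hand. The 2 contigs for translation factors were higher too, neither with an exact p under 0.05.

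RNA processing was mixed, with 4 of 10 contigs higher (40.0%, interval 12.2% to 73.8%, percentile 15.6). It held 4 proteins of the Sm and LSm families, which form the core of spliceosomal particles, a subgroup chosen after the values were seen. LSM7 was 4.85-fold lower (1.31 to 26.8) and SMPF 2.83-fold (1.02 to 8.98). SMP8, at 2.73-fold lower (0.761 to 12.1), and LSM2, at 2.18-fold (0.657 to 8.29), had intervals that reached past equal levels. An RNA-binding protein similar to a defense-related one was 24.8-fold lower (2.80 to 766), on 0.731 reads against 14.9.

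Of 12 contigs matched as transporters 9 were higher (75%, interval 42.8% to 94.5%, percentile 89.6). ZRT3, a zinc transporter, was 3.05-fold higher (2.17 to 4.38), and NAR5, a nitrate transporter, 2.24-fold (1.31 to 4.04). DUR3A, a urea transporter, was 2.51-fold lower (1.26 to 5.32). The match with the largest fold, AGO2 at 6.76 (0.742 to 260), carried a description that joined different proteins. PMH1, a proton-pumping ATPase, was 6.73-fold lower (2.79 to 24.01) and lay outside the list's wording. In nitrogen and amino acid metabolism 2 of 3 contigs were higher, with AAT2, an alanine aminotransferase, at 2.53-fold (1.36 to 5.01). A sulfite reductase contig, from sulfur assimilation, was 6.24-fold higher (1.82 to 31.6), and OASTL1, which makes cysteine, 2.54-fold (1.35 to 4.78).

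Protein folding and turnover genes were listed in both directions. Of 6 contigs for chaperones and heat shock 2 were higher (interval 4.33% to 77.7%, percentile 16.5), and FKB62, a prolyl isomerase, was 4.04-fold lower (1.57 to 12.3). In proteolysis 5 of 10 were higher (interval 18.7% to 81.3%, percentile 30.9), with UBC10, a ubiquitin carrier, at 3.57-fold (0.982 to 19.6), and 5 lower, with the DEG2 protease at 2.73-fold (0.761 to 12.1). An exact p under 0.05 was reached by 4 of the 5 higher contigs and 0 of the 5 lower ones. The antioxidant list held 1 contig, a glutathione S-transferase at 2.47-fold higher (0.75 to 10.5).

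The remaining lists were small. Of 3 contigs each, 2 were higher for kinases, phosphatases and signalling, for transcription factors, for vesicle traffic and for vitamins and cofactors. The largest were a RAN GTPase activating protein at 3.57-fold (1.44 to 10.6), a DnaJ and Myb-like domain protein at 3.30-fold (1.06 to 13.6), GOS1, a Golgi SNARE, at 4.12-fold (0.879 to 38.7), and OASTL1, matched to vitamins by its letters. Of the 2 contigs matched to glycerol and osmoregulation 1 was higher, but both belong to glycerolipid metabolism. No listed contig matched transposons and viral sequences or the names of bacterial, fungal or animal contaminants. Since every name is that of a Chlamydomonas reinhardtii best hit, a contaminant's name could hardly appear. The absence of such names therefore says nothing about contamination. Outside the lists, ERD2A, a receptor that returns proteins to the endoplasmic reticulum, was 6.60-fold higher (1.55 to 59.2). A nuclear transport factor 2 family protein was 13.2-fold higher (2.05 to 553) and a protein similar to B-cell receptor-associated 31 was 8.25-fold higher (1.17 to 358), both with 1 read at 4 h. Of the 43 contigs with no annotated function 20 were higher (46.5%, interval 31.2% to 62.3%), at percentile 5.31.

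**Figure D2:**
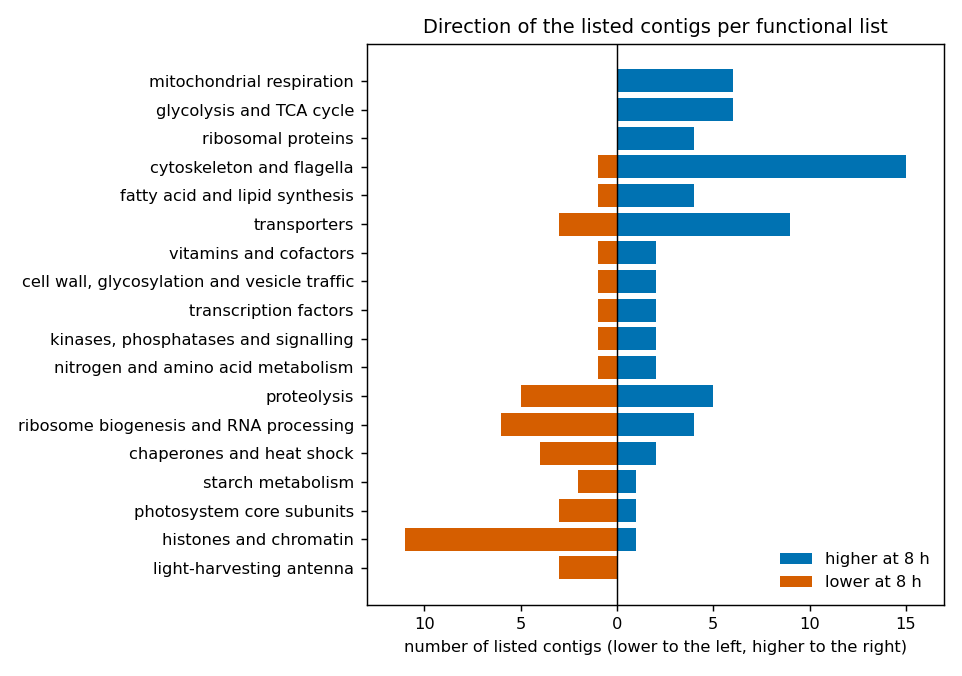
Number of listed contigs per functional list with at least 3 contigs, lower at 8 h to the left and higher to the right of 0. The cytoskeleton and flagella bars hold 15 higher and 1 lower contig, and the histone and chromatin bars 1 higher and 11 lower.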

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

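All tests in this part were chosen after the values they use had been seen. The raw totals held more reads than the 4 h and 8 h libraries supply. Over the 234 contigs, 1591 of 10451 raw reads (15.2%) belonged to neither library, and in 107 contigs the excess was over the 3 reads that a count of 0 allows. The excess was 9.72% of the reads in the higher list and 20.7% in the lower list. Of the 1084 excess reads in the lower list, LHCBM4 alone held 375 and LHCBM3 131. Contigs with an excess over 3 reads were 57 of 134 in the higher list and 50 of 100 in the lower list. The excess reads come from other libraries in the authors' model, which the labels used here do not describe.

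The excess in RPKM is a sum over an unknown number of other libraries, so it cannot be set against the level of a single library. LHCBM4 had the highest, 1851 RPKM, beside authors' means of 123.5 RPKM at 8 h and 256.8 at 4 h. LHCBM3 had 579.5 RPKM there, beside 16.04 and 109.6. A hypothetical protein contig of 798 bases had 351.7 RPKM, beside 11.0 and 32.5. A contig similar to Crd1, a cyclase of chlorophyll synthesis, had 243.0 RPKM, beside 42.1 and 92.8. As a share of raw reads the excess was 71.2% for the hypothetical protein, 60.8% for LHCBM3, 60.2% for LHCBM4 and 36.2% for the Crd1-like contig. The highest single library for LHCBM3 held 96.1 reads and was neither of the time points, and 35.3 further reads remained outside it, so at least 2 other libraries were in the model. Their light and time were not analysed here.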

How the results depend on the processing

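The exact test, the FDR under 0.05, the E value and the hand-read lists were chosen after the data were seen. Among the alternative values for counts, medians and list shares, 170 were the same as the main value, and 28 were not. A count was called the same within 1.5 times, and a median or share within its 95% interval. For lists of few contigs that interval is wide, as 2.5% to 100% for chlorophyll and haem synthesis, so sameness there says little. None of the alternative values crossed the share of all contigs where the interval excluded it. Only the flagella list and the histone list had such an interval. Most alternatives only dropped contigs from these lists, which went nearly all one way, so a crossing was hardly possible. Collapsing repeated names changed no list share. Of the 134 higher contigs, 25 were left at 4-fold, 5 at an FDR under 0.001 and 43 at an FDR under 0.05 in the authors' deposited table, and 78 by the exact test. Of the 100 lower contigs, 11, 13, 33 and 64 were left, since each limit removes contigs by construction. The median log2 ratio of the higher contigs was 1.35 with a pseudocount of 1 RPKM, which shrinks ratios of low values. At 4-fold the share of higher contigs was 0% for photosystem core subunits, histones and chaperones, and 100% for starch, flagella, transporters and vesicle traffic, with 1 to 5 contigs each. By the exact test it was 0% for photosystem core subunits, histones and glycerol, 100% for proteolysis and transcription factors, and 23.8% for unannotated contigs. With an E value under 1e-20 it was 100% for lipid synthesis and glycerol. Against the annotated background the antenna, replication and cell cycle lists lay at -59.7 percentage points, since that background is 59.7% higher in place of 57.3%. Other causes were not tested. All 62 ratios of named genes with a pseudocount stayed within their counting intervals. A pseudocount cannot reverse a ratio and many of these intervals are wide, so this says little about the ratios. No paired analysis was possible because each time point had 1 library. Depth limits single contigs, and 56 higher and 36 lower ones were not separable from equal levels on their reads.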

Other observations

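Contigs outside the wording of the fixed lists, chosen after their values were seen, added to several groups. In traffic between the endoplasmic reticulum and the Golgi, SEC22, a SNARE, was 4.54-fold higher in the 8 h library (0.990 to 42.1), CGL49, an ADP-ribosylation factor, 4.15-fold higher (1.48 to 13.3) and ERD2C 4.12-fold higher (0.879 to 38.7). Read by hand, 8 of 9 contigs of the vesicle traffic list were higher, 17 of 19 for the cytoskeleton and flagella (89.5%) and 1 of 4 for starch. The same reading gave 13 of 14 lower for histones and chromatin, 4 of 5 for the cell cycle and 4 of 4 for DNA replication. The last held RFC3, a clamp loader subunit, at 2.60-fold lower (0.997 to 7.53), and a contig similar to a GINS complex subunit, at 2.91-fold (0.954 to 10.5). A contig similar to TPX2, a spindle assembly factor, was 3.15-fold lower (1.05 to 11.3). Against that direction, a microtubule-associated protein 65-8 contig, of a family that acts in cytokinesis, was 3.15-fold higher (1.90 to 5.29).

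Single genes of metal transport, for which no separate list was fixed, were listed in both directions. Some, as ZRT3, were already counted in the transporters list and add nothing to it. Besides ZRT3, the contigs for magnesium transporter 10, at 4.12-fold (1.17 to 22.2), CAX1, at 3.30-fold (1.20 to 11.2), and ZRT5, at 2.61-fold (1.003 to 7.99), were higher in the 8 h library. Those for a vacuolar iron transporter, at 3.70-fold (0.808 to 41.9), MTP2, at 2.73-fold (1.13 to 7.25), FRE1, a ferric reductase, at 2.66-fold (1.28 to 6.56), and MTP1, at 2.42-fold (0.755 to 9.04), were lower. PHO1, an alkaline phosphatase, stood at 224 RPKM at 8 h and 111 at 4 h. An unannotated contig, CHLREDRAFT_184660, was 36.3-fold lower on 1.27 reads against 38.0 (7.78 to 1867).

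All tests in the following paragraphs were chosen after the values they use had been seen. Flagellar contigs were mostly higher and chromatin, replication and division contigs mostly lower at 8 h. Contig length as the whole cause is argued against. Under 1200 bases, 6 of 6 flagellar contigs were higher (interval 54.1% to 100%) and 0 of 11 chromatin, replication and division contigs (0% to 28.5%), though histone contigs share reads and are not independent. Among longer contigs, 9 of 10 and 1 of 5 were higher. With 15 of 16 and 1 of 16 higher at all lengths, these shares were nearly fixed in advance. They show only that both sets held contigs on each side of the split, and lengths within a class were not matched. Outside both lists, 61.2% of the shorter contigs (51.9% to 69.9%) and 54.3% of the longer ones (42.9% to 65.4%) were higher. Whether the authors' use of RPKM values as counts made this pattern was not decided. The exact test on reads left 142 of the 234 contigs, 54.9% of them higher. It left 12 of the 16 flagellar contigs and 13 of the 16 for chromatin, replication and division. Of these, 11 of 12 flagellar contigs were higher (91.7%, interval 61.5% to 99.8%) and 0 of 13 chromatin, replication and division contigs (0% to 24.7%). Passing the test cannot change a contig's direction, and 15 of 16 and 1 of 16 were higher before it. The shares were thus nearly fixed in advance and cannot decide the question. The authors had chosen all 142 contigs for a large difference first, and the chromatin, replication and division set includes histone contigs with shared reads. Time, culture state and library differ together with 1 library per time point, and no biological explanation was tested.

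The histone contigs may be lower partly because reads moved between near-identical copies. Of 8 histone contigs that were lower, 0 had a whole raw total, which is what shared reads need. An unlisted copy that gained the reads was not tested for, since contigs outside the lists were not analysed here. The flagellar contigs differ in this, as 14 of the 15 higher ones had whole totals.

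Whether few reads in the lower library inflated the largest fold changes stays open. Of the 20 contigs with the largest folds, 10 per direction, 15 had a counting interval that reached below the median fold of their list, but so did 229 of all 234 (97.9%). Of the 20, 16 had 3 reads or fewer in the lower library after rounding.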
